A study of Cricetulus griseus with 9 samples.

How the data were processed

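RNA was sequenced from CHO-K1 cells, a Chinese hamster ovary line, 48 h after lipid transfection with 1 of 3 small RNAs, each with 3 libraries. Per the labels' protocols, stranded poly(A) mRNA libraries were made from 2 µg of total RNA and read as single reads of 75 to 76 cycles on a NextSeq500. The series text says that transfections were done in separate experiments. Its wording does not settle whether each experiment held all 3 molecules or only 1. If each held only 1, experiment and group cannot be told apart. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Untreated cells and cells given a control RNA were not analysed here.

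The values used were FPKM per gene and library, deposited by the authors as 1 table of 15557 genes. FPKM are fragments per kilobase of gene model, divided by a measure of library size. Per the submitters' processing notes, reads were checked with FastQC, aligned with TopHat2 2.0.13 and quantified with Cuffnorm. The Cuffnorm version, its library scaling, the strand setting and any filters are not given in the sources used here. The series text also names a BWA route with an analysis of variance and a TopHat route with Cuffdiff at isoform level. Values from those routes were not used here. Per the file headers, the gene models are mouse proteins of Ensembl release 66 aligned to the hamster assembly CriGri_1.0. Their exon starts and ends came from the deposited annotation, and 99.87% of model lengths were multiples of 3. Lengths are therefore coding lengths, and untranslated regions are outside the models. Reads from hamster transcripts were counted only where a mouse protein aligned.

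Genes carry mouse Ensembl identifiers, and the files do not pair them with names. None of the 15557 identifiers matched the RefSeq gene table of assembly CriGri-PICRH-1.0 (0 matches among 32251 genes), so no gene names are given. For the same reason the 18 gene lists chosen for this treatment could not be tested, nor could a search for miR-29 seed sites, which also needs untranslated regions.

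Depth was read from the low values. In genes of at least 3000 coding bases with 1 model and no shared exon bases, FPKM times length fell in steps of 1 read, and 99.1% to 100% of values of up to 5 reads lay within 0.2 reads of a whole number. The step gave 15030000 to 20710000 implied reads per library, in the unit Cuffnorm divided by, which can differ from the reads sequenced. At the median coding length of 1315.5 bases, 1 FPKM stood for 19.8 to 27.2 reads.

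Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances that follow a trend in mean level. Fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 9 libraries were tested, which left 9504. All 9 libraries entered 1 fit with a term per group. The tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were each pre-miR against anti-miR-29a, the mean of both pre-miRs against anti-miR-29a, and pre-miR-29b-1 against pre-miR-29a. Groups, comparisons, filter, pseudocount and most alternatives were chosen before the data were examined. The rule for genes to name took those with the largest rise and fall among genes past the threshold, with a mean of at least 5 FPKM, no overlap between the libraries compared, and a symbol. With no symbols, that last condition was dropped and 2 identifiers each way were taken from the comparison of both pre-miRs with anti-miR-29a. ENSMUSG00000031167 was added after its values were seen. The test was checked on simulated data for the 9504 genes. For pre-miR-29b-1 against anti-miR-29a it recovered 82% of 100 genes changed 1.5-fold and 96% of 100 changed 2-fold, with 8 calls among unchanged genes. For pre-miR-29b-1 against pre-miR-29a the shares were 83% and 96%, with 7 such calls. The simulated libraries were independent, and each gene had the same spread in all of them. The real libraries were less even, with estimated weights of 0.213 to 3.54, so these shares may be too high for them.

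Since both pre-miR comparisons use the same anti-miR-29a libraries, chance values for their overlap came from 20 simulated sets of unchanged groups with each gene's residual variance. Alternatives changed the pseudocount, the filter, the scaling, the variance model, library weights, the libraries in the fit and the replicate number as a block, and left out each library in turn. Restricting the genes to those with 1 model and no shared bases was chosen after seeing the data. Cell cycle phase markers were also chosen after the data were seen. They are the mouse Ensembl identifiers of the marker pairs distributed with the scran package, kept where a gene was the higher member for 1 phase alone, which gave 57 genes for G1, 101 for S and 53 for G2M. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other calculations.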

Results

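Transcript levels were measured in CHO-K1 cells that received anti-miR-29a, pre-miR-29a or pre-miR-29b-1, with 3 libraries per group. The pre-miRs are synthetic precursors that raise the level of the microRNA they are named for, and the anti-miR is an inhibitor described by the submitters as acting on both miR-29a and miR-29b-1. MicroRNAs of the miR-29 family share a seed, the part that pairs with target mRNAs, and lower the level or translation of those targets. The libraries ask which transcripts respond to more or less miR-29 and whether the family members differ in their effect. Implied depth averaged 19710000 ± 1040000 reads (SD, n = 3) for pre-miR-29b-1, 18030000 ± 1300000 reads for pre-miR-29a and 16650000 ± 1460000 reads for anti-miR-29a. Correlations of log2 values across genes lay between 0.988 and 0.995 within groups, between 0.982 and 0.993 across the pre-miR groups, and between 0.961 and 0.971 for pre-miR against anti-miR-29a libraries. The first principal component held 60.8% of the variance and set the anti-miR-29a libraries, at 30.3 to 31.9, apart from the pre-miR libraries, at -18.2 to -13.4.

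With pre-miR-29b-1, ENSMUSG00000024538 stood at 16.9 ± 0.41 FPKM (SD, n = 3) against 241.7 ± 4.24 FPKM with anti-miR-29a. ENSMUSG00000070436, an abundant transcript, stood at 489.6 ± 6.73 FPKM against 3399 ± 184 FPKM. In the other direction, ENSMUSG00000074676 stood at 131.6 ± 13.8 FPKM against 31.3 ± 7.08 FPKM, and ENSMUSG00000027338 at 13.8 ± 0.89 FPKM against 3.43 ± 0.40 FPKM. The log2 fold changes were -3.76 (SE 0.044) for ENSMUSG00000024538 with an adjusted p of 2.02e-11 (limma, Benjamini-Hochberg) and -2.79 (SE 0.056) for ENSMUSG00000070436 with an adjusted p of 1.29e-09 (limma). They were 2.05 (SE 0.136) for ENSMUSG00000074676 with an adjusted p of 1.37e-06 (limma) and 1.74 (SE 0.088) for ENSMUSG00000027338 with an adjusted p of 2.35e-07 (limma). Each was seen in 3 of 3 libraries of either group, without overlap, which the rule for choosing these genes required.

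On the CriGri_1.0 assembly, ENSMUSG00000024538 lies on scaffold JH000456 from 374214 to 379660 on the minus strand, with 5 coding exons, and ENSMUSG00000070436 on JH002044 from 75201 to 78164, minus strand, with 4. ENSMUSG00000074676 is a single coding exon on JH000311 from 1121275 to 1122264, plus strand, and ENSMUSG00000027338 a single coding exon on JH000136 from 607256 to 607792, minus strand. Each of these genes had 1 model that shared no exon bases with another gene. The lowest value among them, ENSMUSG00000027338 with anti-miR-29a, rested on 24 to 35 implied reads per library.

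Across all genes, 5246 of the 9504 tested differed between pre-miR-29b-1 and anti-miR-29a, of which 2451 were higher and 2795 lower with pre-miR-29b-1 (limma). This balance turned with quantile normalization, to 3170 higher and 2474 lower. Most changes were small, with 3723 of the changed genes under 1.5-fold. Among genes changed at least 2-fold, 93 were higher and 328 lower, so that 77.9% were lower. Libraries did not overlap between the groups for 67.6% of the tested genes, where chance gives 10% for 3 against 3. The median log2 fold change over all tested genes was -0.006.

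With pre-miR-29a, the same named transcripts were lower or higher than with anti-miR-29a. They were chosen from both pre-miRs together, which required this, so it is not separate evidence that the pre-miRs act alike. ENSMUSG00000024538 stood at 18.2 ± 0.24 FPKM (SD, n = 3) and ENSMUSG00000070436 at 532.7 ± 14.6 FPKM, against the anti-miR-29a values of 241.7 ± 4.24 and 3399 ± 184 FPKM. ENSMUSG00000074676 stood at 92.7 ± 6.50 FPKM and ENSMUSG00000027338 at 13.96 ± 0.87 FPKM, against 31.3 ± 7.08 and 3.43 ± 0.40 FPKM. The log2 fold changes were -3.66 (SE 0.044) for ENSMUSG00000024538, -2.67 (SE 0.056) for ENSMUSG00000070436, 1.56 (SE 0.136) for ENSMUSG00000074676 and 1.76 (SE 0.088) for ENSMUSG00000027338. The highest adjusted p among them was 7.37e-06 (limma, Benjamini-Hochberg), for ENSMUSG00000074676.

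Over all tested genes, 5553 differed between pre-miR-29a and anti-miR-29a, with 2613 higher and 2940 lower (limma), and with 3340 higher and 2494 lower after quantile normalization. Of these, 3873 changed by under 1.5-fold. At least 2-fold, 91 genes were higher and 405 lower, which makes 81.7% lower. Groups did not overlap for 62.2% of tested genes, against 10% by chance.

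**Figure D1:**
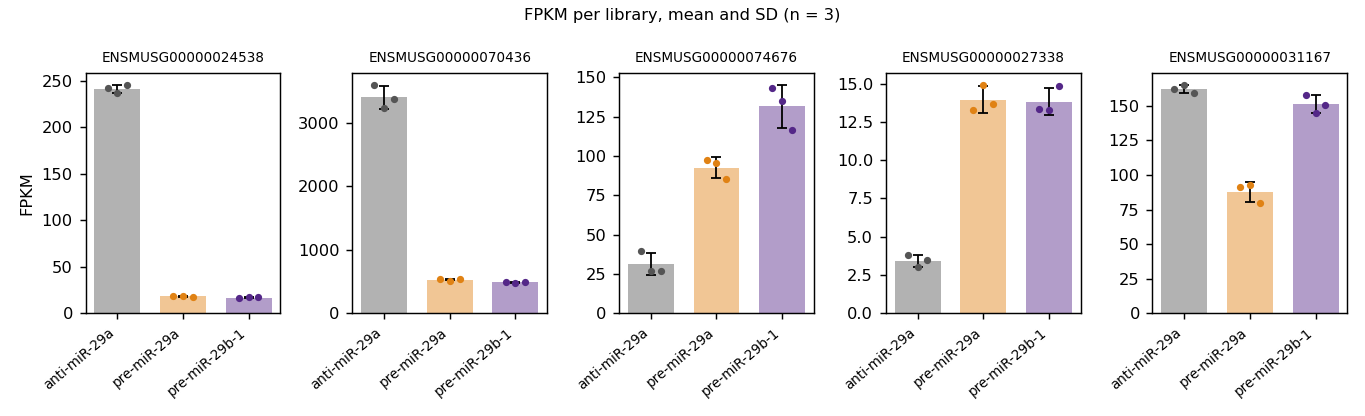
FPKM of 5 genes in each of the 3 groups, with bars for the mean, error bars for the SD and points for the 3 libraries. ENSMUSG00000024538 and ENSMUSG00000070436 are lower with both pre-miRs than with anti-miR-29a, and ENSMUSG00000074676 and ENSMUSG00000027338 are higher. ENSMUSG00000031167 passed the test as lower than with anti-miR-29a for pre-miR-29a but not for pre-miR-29b-1.

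Taking both pre-miRs against anti-miR-29a, 362 genes were at least 2-fold lower and 78 at least 2-fold higher, so 82.3% of the strongly changed genes were lower. With a pseudocount of 0.1 in place of 1 the numbers were 417 lower and 169 higher, and with 5 they were 248 and 23. The 362 lower genes held 4.27% ± 0.11 of all FPKM with anti-miR-29a (SD, n = 3), 1.61% ± 0.018 with pre-miR-29b-1 and 1.52% ± 0.073 with pre-miR-29a. The 78 higher genes held 0.107% ± 0.0037, 0.267% ± 0.0093 and 0.275% ± 0.015 in the same groups. Both sets were chosen by their change in these same libraries, so the direction of these shares follows from the choice and is not separate evidence. In all, 5857 genes changed, 2783 higher and 3074 lower (limma), and 4289 of them by under 1.5-fold. The log2 fold change of ENSMUSG00000024538 was -3.71 (SE 0.038) with an adjusted p of 5.64e-12 (limma), and that of ENSMUSG00000070436 -2.73 (SE 0.048) with an adjusted p of 3.92e-10 (limma).

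Among genes changed at least 2-fold, lower ones outnumbered higher ones at each level of mean FPKM tested, from 1 FPKM upward. Under 1 FPKM, outside the tests, 414 genes had all pre-miR libraries above all anti-miR-29a libraries and 65 the reverse. In 4 bins of 2376 genes by mean FPKM, the lowest bin held 47 genes at least 2-fold higher and 88 lower. In the next bins the numbers were 18 and 101, then 9 and 102. In the bin with the highest levels, from 94.4 FPKM upward, 4 genes were higher and 71 lower. The bins were counted on the log2(FPKM + 1) scale alone, which shrinks changes of low genes. The numbers in the lowest bin, and the trend over the bins, may depend on that. Between 53.6% and 67.2% of the genes of a bin changed at any size. Quantile normalization moved the median log2 fold change by less than 0.1 but left 42.7% of all changed genes lower in place of 52.5% (3529 higher and 2627 lower), with 99 genes at least 2-fold higher and 301 lower.

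The differences of each pre-miR from anti-miR-29a were compared across genes. Of the 9504 genes, 2058 were higher and 2475 lower in both comparisons with anti-miR-29a, and 0 were called in opposite directions. Lists of the same sizes drawn independently would share 673.9 higher and 864.6 lower genes and would hold 1526.6 genes in opposite directions. Simulated unchanged groups shared 0 called genes, which says little because they gave 0.05 calls per comparison on average. The covariance of the log2 fold changes across genes was 0.215. Simulated unchanged groups against the same libraries gave 0.0136 on average, which leaves 0.201. Subtracting instead the part due to the residual variance of the anti-miR-29a libraries, obtained separately, left 0.202. Pearson's r across genes was 0.916 and Spearman's rho 0.917, against 0.515 and 0.460 in the simulation. Genes are not independent replicates, and with 3 anti-miR-29a libraries no split into groups of at least 2 was possible, so part of the overlap may come from the shared libraries. Both comparisons subtract the same anti-miR-29a group, so a change in that group alone would give such an overlap as well.

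**Figure D2:**
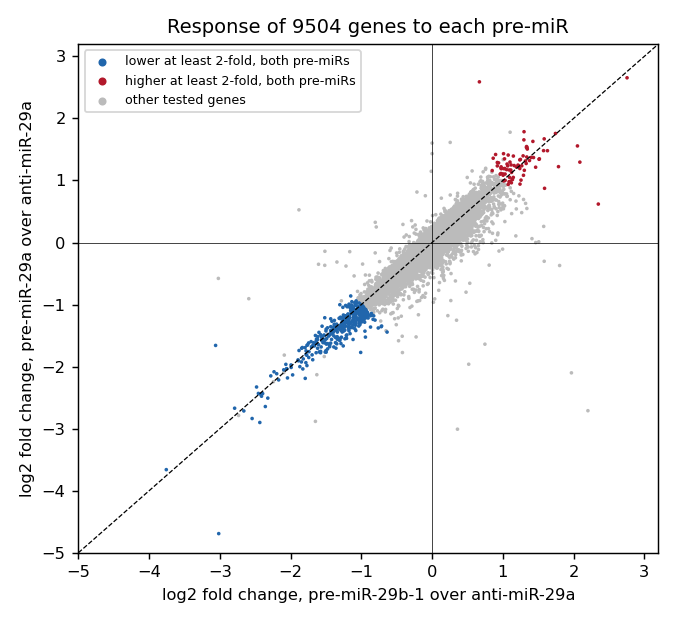
Log2 fold change of 9504 genes with pre-miR-29b-1 (horizontal axis) and with pre-miR-29a (vertical axis) over anti-miR-29a, on the log2(FPKM + 1) scale, with a dashed line of equal response. Blue points are the 362 genes at least 2-fold lower and red points the 78 at least 2-fold higher with both pre-miRs together, and 0 genes passed the test in opposite directions.

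Pre-miR-29b-1 and pre-miR-29a differed in the level of ENSMUSG00000031167. It stood at 151.1 ± 6.55 FPKM (SD, n = 3) with pre-miR-29b-1, 162.3 ± 2.95 FPKM with anti-miR-29a and 87.9 ± 7.33 FPKM with pre-miR-29a. The log2 difference between the pre-miRs was 0.78 (SE 0.063) with an adjusted p of 0.00282 (limma, Benjamini-Hochberg), without overlap in 3 against 3 libraries. Against anti-miR-29a, ENSMUSG00000031167 was lower with pre-miR-29a, at -0.88 (SE 0.063, adjusted p 2.08e-06, limma), and stood at -0.10 (SE 0.063, adjusted p 0.192, limma) with pre-miR-29b-1. The gene lies on scaffold JH000543 from 839716 to 841390, minus strand, with 5 coding exons and 1 model that shares no bases, and was named after its values were seen because it was the single gene past the threshold. Its call ended without moderation of the variances (adjusted p 0.209, limma) and in a fit of the pre-miR libraries alone (adjusted p 0.0649, limma).

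For most genes the difference between the pre-miRs was small. The 95% interval of the difference lay within 1.5-fold for 92.7% of the tested genes and within 2-fold for 97.8%. Of the 440 genes changed at least 2-fold with both pre-miRs together, 393 had an interval of the difference within 1.5-fold, and the median absolute log2 difference was 0.12. At an unadjusted p under 0.05 (limma), 1570 genes differed, a larger share of the tested genes than 0.05. Libraries of the pre-miR groups did not overlap for 18.9% of the tested genes, above the chance share stated for the other comparisons. Small differences may therefore be more common than the count of 1 gene shows. That count was not stable. With the replicate number as a block, 184 genes passed, 168 higher and 16 lower with pre-miR-29b-1. Without pre-miR-29a replicate 1, 1370 genes passed, with a median absolute log2 difference of 0.27 and 9 genes at or above 2-fold, and with library weights, which gave pre-miR-29a replicate 1 a weight of 0.213 and replicate 3 a weight of 3.54, 3627 genes passed.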

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

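The comparisons of low genes were chosen after the number of detected genes was seen, as were 2 of the tests on the excess of lower genes, at high levels and in genes with single models.

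ENSMUSG00000031167 had a log2 difference of 0.78 between pre-miR-29b-1 and pre-miR-29a in a test of the difference itself (adjusted p 0.00282, limma). The adjusted p was 0.209 without moderation and 0.0649 with the pre-miR libraries alone (limma), and another of the 10 splits of these 6 libraries also gave 1 gene.

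Genes outside the tests, with a mean under 1 FPKM, were more often detected with a pre-miR than with anti-miR-29a. Of 3872 such genes with any value above 0, 414 had all 6 pre-miR libraries above all 3 anti-miR-29a libraries and 65 had the opposite order. Chance would give 46.1 each way for interchangeable libraries without tied values. Ties at 0 make the chance number lower by an amount not computed, and the libraries differed in depth. Neither count was therefore tested against chance. In 2546 of them with single models, reads per 1000000 implied reads averaged 670.5 ± 5.95 (SD, n = 3) with pre-miR-29b-1, 642.7 ± 23.6 with pre-miR-29a and 434.2 ± 10.8 with anti-miR-29a. Listed at 0 in all 3 anti-miR-29a libraries and above 0 in all 6 pre-miR libraries were 51 genes, and 2 genes showed the reverse. The 51 genes lie near the limit of detection, with a median of 0.087 FPKM over the pre-miR libraries and a highest mean of 0.391 FPKM. In genes with single models the counts were 41 and 0. Poisson draws at the implied reads, with the same rate for a gene in all libraries, gave 2.2 and 1.3 on average.

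Over all genes, 11941.5 were above 0 on average in the pre-miR libraries and 11369.0 in the anti-miR-29a libraries, a gap of 572.5 (two-sided exact permutation p 0.0119, the smallest that 84 regroupings can give). Lower depth with anti-miR-29a is argued against, because draws at the implied reads gave 14.8% of the gap in genes with single models and because this share of reads, which does not depend on depth, differed 1.51-fold. Genes in the main tests held 0.2% of the gap, but 99.9% of their values are above 0, so this says nothing about their changes. Trace genomic DNA in the pre-miR libraries, which would add evenly to all genes, stays open: 1.55 times as many genes were at 0 in all 6 pre-miR libraries as an even excess predicts, with a bootstrap interval of 1.38 to 1.72 that includes the limit of 1.5 set for it and was added after the ratio was seen, and genes to which reads cannot map would raise this ratio too. A response of weakly transcribed genes to miR-29 and a difference between transfection experiments or RNA preparations also stay open, and the latter cannot be separated from the groups if each molecule had its own experiment.

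The excess of lower genes among those changed at least 2-fold is a pattern that library scaling or shared reads could produce. After quantile normalization 75.2% were lower, above the limit of 70% set for scaling as the whole cause, though under the 82.3% of the deposited scaling. In the upper part of genes by mean FPKM, where depth matters least, 93.0% were lower, and in genes with single models and no shared bases 83.7%. These values argue against each as the whole cause. Lowering of targets by miR-29, release of targets by the anti-miR, and a difference between experiments remain candidate explanations that these libraries cannot separate, since untreated cells were not analysed here.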

How the results depend on the processing

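The counts of genes changed against anti-miR-29a stayed within 1.5 times under every alternative run, with 3987 to 6507 for pre-miR-29b-1, 4219 to 6790 for pre-miR-29a and 4437 to 6894 for both. The lowest of these came from genes with 1 model and no shared bases, 6954 of the 9504 tested, so they are not by themselves a loss of calls. Leaving out 1 library gave 4504 to 4785, 4856 to 5876 and 5088 to 6224. The balance of all changed genes turned from more lower to more higher with quantile normalization in each comparison with anti-miR-29a, and for both pre-miRs also with median of ratios rescaling (2959 higher, 2932 lower) and without a filter (3141 and 3048). No named gene changed direction. Pre-miR-29b-1 against pre-miR-29a gave 1 gene, but 3627 with array weights, 184 with the replicate block, 0 without moderation and 0 with only the groups compared, and 1 to 1370 when 1 library was left out, the highest without pre-miR-29a replicate 1. The percent lower among genes changed at least 2-fold was 82.3, but 71.2 with a pseudocount of 0.1, 91.5 with 5, 87.0 with a filter at 5 FPKM, 79.8 with median of ratios rescaling, 75.2 with quantile normalization, 80.9 with array weights, 83.7 in genes with 1 model and no shared bases, and 78.5 to 82.9 without 1 library. The covariance of the pre-miR responses, less the part due to the shared libraries, was 0.2017, but 0.2485 with a pseudocount of 0.1, 0.1454 with 5, 0.1499 without a filter, 0.1972 with a filter at 5 FPKM, 0.1982 with quantile normalization, 0.2058 in genes with 1 model, and 0.1977 to 0.2062 without 1 library. A larger pseudocount shrinks changes of low genes by construction, and otherwise the cause was not tested. Same-numbered libraries of different groups deviated together with r of -0.02 to 0.29, with 6 of 9 pairs over 0.1. The 18 pairs of different numbers reached at most 0.09. Pairs of replicate 1 libraries had r of 0.29, 0.21 and 0.14, and 4 of 9 libraries correlated best with their own number in both other groups. These values point to a deviation shared by number, though not in every pair. The main fit, planned without a block, does not account for it. The replicate block gave 5552, 5870 and 6167 genes against anti-miR-29a. Of 98 alternatives on single named genes, 96 kept the call and 2 ended it, both for ENSMUSG00000031167.

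In other splits of the libraries, for pre-miR-29b-1 against anti-miR-29a 1 of 10 splits, the real one, gave as many genes (5246, highest other 1), and for pre-miR-29a 1 of 10 (5553, highest other 1). For pre-miR-29b-1 against pre-miR-29a it was 2 of 10 (1, highest other 1). With 10 splits a share under 0.05 cannot be reached. For both pre-miRs 1 of 100 drawn splits gave as many (5857, highest other 3524). The 3 next highest kept the anti-miR-29a libraries together, and the 96 parting them gave at most 1. This shows that these libraries are alike, not why. Gene list tests and the seed site test were not run.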

Other observations

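The tests in this part were chosen after the data were seen, and those of gene neighbours and gene span after a first look at the same values.

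Genes that mark a phase of the cell cycle changed in both directions, as did tested genes in general, of which 61.6% changed with both pre-miRs against anti-miR-29a. Of 48 tested G1 markers, 10 were higher and 16 lower with both pre-miRs against anti-miR-29a, of 81 S markers 28 were higher and 26 lower, and of 41 G2M markers 14 were higher and 15 lower (limma). Adjusted over the list alone, the counts were 10 and 16, 28 and 27, and 15 and 15. The median log2 fold change was -0.09 for G1, 0.02 for S and -0.01 for G2M, with means of -0.09, -0.02 and -0.07, so that median and mean differ in sign for S. Camera, a two-sided test of a set against the other genes, placed G2M and S on the upward side of those genes and G1 on the downward side. None of the sets stood apart from other genes, with an adjusted p of 0.848 at the preset correlation. Camera with an estimated correlation gave a lowest adjusted p of 0.8238 over both single pre-miR comparisons, so no set moved apart from other genes there either. Since most tested genes changed, a test against other genes cannot exclude a different mix of phases. By fry, which does not compare a set with other genes, the outcome depended on the scaling. For both pre-miRs the G1 markers moved down on balance with the deposited scaling (adjusted p 0.00766) and with median of ratios rescaling (adjusted p 0.0278). After quantile normalization their median was -0.003 and the call ended (adjusted p 0.907), while S markers, with a median of 0.10, moved up (adjusted p 0.00450). For pre-miR-29b-1 alone the G1 call held with median of ratios rescaling (adjusted p 0.0227, fry). For pre-miR-29a alone it ended (adjusted p 0.143, from 0.0348 with the deposited scaling, fry).

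Neighbouring genes were asked whether they move together. Over 3034 adjacent pairs up to 50 kb apart, with single models, the rank correlation of log2 fold changes was 0.054 (one-sided permutation p 0.001, the smallest that 1000 shuffled orders can give), where the highest shuffled value was 0.054 after rounding. The relation is weak, and pairs with both genes at least 2-fold lower numbered 4 against 4.8 expected from shuffling. A shared response of neighbours may account for a small part of the changes at most.

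Gene span was weakly related to the change over all genes. The rank correlation of span with log2 fold change across genes was -0.089, and -0.109 given mean level and coding length, so neither accounts for it. Genes spanning at least 50 kb had a median log2 fold change of -0.05 and those under 5 kb 0.04. At least 2-fold lower were 49 of 1592 genes spanning at least 50 kb and 83 of 2206 under 5 kb, and the genes at least 2-fold lower had a median span of 14.4 kb against 15.3 kb for all tested genes. Longer genes may also have longer untranslated regions, which were not analysed here.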
